A study of Ilex with 6 samples.

How the data were processed

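Poly(A)-selected leaf RNA of 6 libraries was sequenced as 150-base paired reads. Per the submitters' processing notes, the tools named were fastp, HISAT2 2.0.5 and 2.0.4, StringTie 1.3.3b and featureCounts 1.5.0-p3, with no roles given. The genome build is not given in the sources used here. The deposited table holds 6 value columns, in FPKM by the name the authors gave it. The names of these 6 columns occur nowhere in the labels or the series text, so none could be assigned to WT or YT. The 6 columns were not used, and the expression tests fixed before the data were examined (limma on log2 values, gene set tests and their alternatives) were not run. The depth of the libraries was not analysed here.

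The annotation columns of the same table were used instead: gene identifier, sequence, start, end, strand, gene length, biotype and description. This use was chosen after the table was seen. The sequence number printed is the number at the end of the table's sequence name. Rows with no biotype are called assembled loci. The gene name cell repeated the gene identifier in all 35217 annotated rows. The 22 gene lists, whose text patterns were fixed before the data were examined, therefore matched through the description text (Swiss-Prot and Pfam) alone. The Swiss-Prot text holds an entry code beside the product name, and a pattern can match that code too. Members were not curated, so a list can hold products outside its named pathway, and those given in the report are not a full count. The lists held 2335 genes, 11 of them in more than 1 list. The rule fixed for naming genes needs expression values and could not be applied, so the genes named were chosen after their positions and products were seen.

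A member was called clustered when another member of its list lay within 50 kb on the same sequence, measured between the gene ends. The count was compared with 10000 random lists of the same size drawn from the 29322 rows with Swiss-Prot or Pfam text. The test is a one-sided permutation test, and p-values were adjusted over the 22 lists by the Benjamini-Hochberg method. Members of a gene family share their description and can lie side by side, so random lists are a low baseline for a family, and duplication was not tested. Split gene models also count as neighbours. In simulated data, 50 of 50 lists of about 40 genes, each with several planted neighbouring pairs, were called at p under 0.05. Of 50 random lists of 40, 0 were called. A single planted pair was not simulated. For a list with only 2 clustered members, p is set by the list size, the gap and the rows drawn from. In the permutation test with 50 kb, p was 0.108 for such a list of 33 members. It was 0.0590 and 0.0626 for the 2 such lists of 25 members. With 20 kb it was 0.0263 for both lists of 25. The call of such a list therefore turns on its size and the gap. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used. Alternatives were gaps of 20 kb and 100 kb, leaving out assembled loci, Swiss-Prot text alone, and leaving out the 3 sequences with runs of plastid-type genes.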

Results

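The series holds 6 leaf RNA libraries of 3-year-old hollies, 3 from the green-leaved hybrid cultivar 'Nellie R. Stevens' (WT) and 3 from 'Whoa Nellie' (YT), a bud mutant of it with yellow leaves. The comparison the design implies, WT against YT, was not made. The expression table names its 6 value columns TN and TW, each with a number from 1 to 3, and neither code occurs in the labels. Reading N and W as the initials of the cultivar names and reading TW as WT written backwards assign the columns to opposite groups. Columns that the labels do not identify were left out of every step, so no expression value, depth or fold change is reported, and nothing that follows says which genes differ between green and yellow leaves. What follows describes the genes that the table lists, with their positions and annotated products, for the pigment and plastid pathways that a yellow-leaf comparison would examine.

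The table listed 37776 gene rows on 338 sequences, of which 35217 were annotated protein-coding genes and 2559 were assembled loci that carried no biotype. The 20 sequences with at least 1000 gene rows each held 93.4% of the rows, from 1245 on sequence 11 to 2969 on sequence 14. Swiss-Prot text was given for 25694 rows (68.0%), Pfam text for 26002 (68.8%), and neither for 8454. The median gene length was 1308 bases for annotated genes and 522 bases for assembled loci. All positions are those of the table, on sequences numbered as in it, and the genome build is not given in the sources used here.

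Chlorophyll synthesis was represented by 33 members. They covered the pathway from glutamyl-tRNA reductase, which commits glutamate to tetrapyrrole synthesis and was listed 3 times, to chlorophyll synthase, listed once (Ila19G001260, sequence 19, bases 1834421 to 1839858). The 3 subunits of magnesium chelatase, the enzyme that inserts magnesium into protoporphyrin IX, each had a single gene. ChlH was Ila19G011500 (sequence 19, bases 28207485 to 28213701), ChlD was Ila09G012370 (sequence 9, bases 27987258 to 28007991) and ChlI was Ila15G019570 (sequence 15, bases 50927470 to 50929930). Protochlorophyllide reductase, the light-requiring step, had 4 annotated genes, and an assembled locus with the same product lay within 50 kb of Ila20G010460 on sequence 20. That pair made the list's 2 clustered members, against 0.227 expected for random lists of the same size (permutation test with 10000 random lists, one-sided, p = 0.108, adjusted p = 0.113). With a gap of 100 kb the list had 4 clustered members and passed (permutation test, adjusted p = 0.0205). The pair gained was Ila05G011670 and Ila05G011700, both annotated as glutamyl-tRNA reductase 1. Without assembled loci, at 50 kb, the list had 0 clustered members. Also matched were a uroporphyrinogen III methyltransferase (Ila09G014230) and a protoporphyrinogen oxidase annotated as mitochondrial (Ila14G000520).

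Chlorophyll breakdown had 25 members. They included 4 genes for pheophytinase, 3 for chlorophyllase-2, 2 for pheophorbide a oxygenase, 2 for STAY-GREEN and 2 for the related magnesium dechelatase SGRL. The chlorophyllase-2 genes Ila13G002910 and Ila13G002920 lay side by side on sequence 13 (bases 3228154 to 3237435), and were the list's 2 clustered members (permutation test, p = 0.0590, adjusted p = 0.0683). This call depends on the gap. With 20 kb the list passed on the same 2 members, against 0.0534 expected in place of 0.121 (permutation test, adjusted p = 0.0386). It also passed with 100 kb (adjusted p = 0.000825), where the 3 members gained were accelerated cell death 11 genes. The text pattern also matched 5 genes named accelerated cell death 11, a glycolipid transfer protein. Through the Pfam name of pheophorbide a oxygenase it matched chlorophyllide a oxygenase, an enzyme of chlorophyll b synthesis, and the import proteins TIC 55 (Ila01G011210) and protochlorophyllide-dependent translocon component 52 (Ila17G010470).

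The list named for light-harvesting chlorophyll a/b proteins, the antenna of the photosystems, had 44 members. Of these, 14 (31.8%) had another member within 50 kb, against 0.394 expected (permutation test, p = 0.0001, adjusted p = 0.000183). This p is the smallest that 10000 random lists can give. Not all members were annotated as chlorophyll a-b binding proteins. Light-harvesting complex-like proteins and the photosystem II 22 kDa protein (Ila05G007240) were also matched. The clustered members included Ila03G002680 and Ila03G002690, both annotated as light-harvesting complex-like protein OHP1. Ila16G005220, Ila16G005230 and Ila16G005240, all annotated as chlorophyll a-b binding protein 21, stood within 35.2 kb on sequence 16. A run of 3 early light-induced protein genes, which belong to the same protein family and are known for their induction by strong light, lay on sequence 11 (Ila11G007850, Ila11G007860 and Ila11G007870, bases 25363646 to 25393605). These were members through their Pfam text.

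Carotenoid synthesis had 25 members, from phytoene synthase to zeaxanthin epoxidase. Zeaxanthin epoxidase, which converts zeaxanthin to violaxanthin, was listed 5 times. Of these rows, Ila18G005720 (240 bases) and Ila18G005770 (309 bases) had no Pfam domain, against 2592 bases for Ila06G004140. The rows Ila18G005680 and Ila18G005690 lay within 32.1 kb on sequence 18, and were the list's 2 clustered members (permutation test, p = 0.0626, adjusted p = 0.0688). With a gap of 20 kb the list passed on the same 2 members, against 0.0526 expected in place of 0.128 (permutation test, adjusted p = 0.0386). It also passed with 100 kb, with 3 clustered members (adjusted p = 0.00623), where the member gained was the 240-base row Ila18G005720. Lycopene beta cyclase (Ila03G012540, sequence 3) and lycopene epsilon cyclase (Ila16G024340, sequence 16), which divide the flow between the carotene branches, had 1 gene each by product name. A further row, Ila17G014890, annotated as capsanthin/capsorubin synthase, carried the same Pfam name, lycopene cyclase protein. Pfam text brought in 2 squalene synthases, which make sterol precursors, and an assembly factor of NADH dehydrogenase (Ila15G002900). With Swiss-Prot text alone, which leaves those 3 out, the list had 22 members. It then passed on the same 2 clustered members, against 0.0864 expected in place of 0.128 (permutation test, adjusted p = 0.0493). Among the 16 genes of carotenoid cleavage and abscisic acid synthesis 4 were clustered (permutation test, p = 0.0003, adjusted p = 0.000508), among them the carotenoid cleavage dioxygenase 4 genes Ila01G006520 and Ila01G006530 on sequence 1.

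Flavonoid and anthocyanin enzymes had 40 members, of which 13 (32.5%) were clustered, against 0.326 expected (permutation test, p = 0.0001, adjusted p = 0.000183). The members included 3 fatty-acid-binding proteins, matched through a Pfam name, and 2 homeobox factors named ANTHOCYANINLESS 2, and none of these 5 was clustered. The longest run held 4 genes within 42.9 kb on sequence 9, made up of 3 annotated as anthocyanidin reductase and Ila09G018410, a dihydroflavonol 4-reductase, the enzyme that leads to leucoanthocyanidins. Anthocyanidin 3-O-glucosyltransferase 5 had 5 genes, 3 of them in a run on sequence 10. Phenylpropanoid and lignin enzymes had 114 members, 46 of them clustered (40.4%), with the same p and adjusted p. Among these 46 was a run of 11 laccase rows within 200.6 kb on sequence 5, the longest of the list. Spermidine and putrescine hydroxycinnamoyltransferases were also members of this list.

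Photosystem and electron transport subunits had 88 members, of which 30 (34.1%) were clustered, and chloroplast ribosomal proteins had 95, of which 32 (33.7%) were clustered (permutation test, p = 0.0001 and adjusted p = 0.000183 for each). In both lists together, 58 of the clustered genes lay on 3 sequences, and their products were mainly ones encoded in the plastid genome of plants. Sequence 353 held 33 such clustered genes with 30 different products, including the D1, CP43 and CP47 proteins of photosystem II and the A1 and A2 apoproteins of photosystem I. Another 15 lay on sequence 7 and another 10 on sequence 57. Of the 14 products on sequence 7, 13 also stood on sequence 353, as did 9 of the 10 on sequence 57. The products were matched by name only, and the sequences of these rows were not compared. Lengths of rows with the same product could differ, as for ribosomal protein S18, with 666 bases on sequence 7 and 306 on sequence 353. Outside the 3 sequences, which were picked because they hold these runs, 2 of 59 photosystem members (permutation test, adjusted p = 0.333) and 2 of 63 chloroplast ribosomal members (adjusted p = 0.363) were clustered. Both calls were thus lost without these sequences, but because of how they were picked this is no independent test.

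Random lists are a low baseline for lists that hold gene families, whose members share a description and can lie side by side. Of the 22 lists 18 passed the clustering test at an adjusted p under 0.05. The 4 that did not were chlorophyll synthesis, chlorophyll breakdown, carotenoid synthesis and the chloroplast development list, which had no clustered gene among 40, against 0.319 expected (permutation test, p = 1). With so few expected, none is the usual outcome. That list holds more than regulators, such as the thylakoid proteins CURVATURE THYLAKOID 1 and the division protein FtsZ. It also holds 2 genes named Homeobox-DDT domain protein RLT1 and RICESLEEPER 3 (Ila07G008200). The product and Pfam names of RLT1 and RICESLEEPER 3 contain none of the list's terms. These genes matched through other parts of the Swiss-Prot text. Of the 4 lists that did not pass with 50 kb, chlorophyll synthesis passed with a gap of 100 kb. Breakdown and carotenoid synthesis passed with both 20 kb and 100 kb. The number expected by chance rises with the size of a list, so shares of lists of different size are not ranked here. Defence and pathogenesis-related proteins had 325 of 597 members clustered, against 68.8 expected, and heat shock proteins 58 of 178, against 6.45. Vascular and secondary wall markers had 27 of 65, against 0.848, epidermis and cuticle markers 39 of 91, against 1.66, and senescence markers 35 of 89, against 1.62. Circadian clock genes had 10 of 41, against 0.347, antioxidant and photoprotection proteins 9 of 47, against 0.442, and plastid isoprenoid enzymes 4 of 30, against 0.179. The longest antioxidant run, 3 members on sequence 11, spans the same bases as the early light-induced run of the light-harvesting list. Cytosolic ribosomal proteins had 41 of 309, against 19.1, dividing-cell markers 26 of 221, against 9.91, the Calvin cycle list 4 of 51, against 0.532, and plastid protein import and proteases 8 of 107, against 2.35. With a gap of 20 kb in place of 50 kb, 5 of the lists that passed no longer did (permutation test), and their shares were 6.67% for plastid isoprenoid enzymes (adjusted p = 0.0522), 4.88% for circadian clock genes (adjusted p = 0.0869), 4.53% for dividing-cell markers (adjusted p = 0.0853), 3.92% for the Calvin cycle list (adjusted p = 0.118) and 3.74% for plastid import and proteases (adjusted p = 0.107). The last of these also did not pass with 100 kb (adjusted p = 0.0699) or without assembled loci (adjusted p = 0.109). It also held 13 members annotated as mitochondrial alone, and of its 8 clustered members 2 were assembled loci matching the mitochondrial chaperone ClpB4 on sequence 15. Of the Calvin cycle members 14 were uridine kinases and inorganic pyrophosphatases matched through a Pfam name shared with phosphoribulokinase. Its 4 clustered members were a single run of Rubisco activase rows on sequence 19, and 3 of these had no Pfam domain. The test describes where the listed genes lie and carries no information on their expression.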

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

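All of these alternatives were chosen after the table was seen. Against 18 of 22 lists in the reported setting, 15 lists passed the clustering test with a gap of 20 kb, 20 with a gap of 100 kb, 17 without assembled loci, 19 with Swiss-Prot text alone and 16 without the 3 sequences with plastid-type runs, of which sequence 7 also carries other genes. The call of 7 lists changed with 20 kb, of 4 with 100 kb, of 2 (photosystem and chloroplast ribosomal) without the 3 sequences, which were picked for their runs of these lists, and of 1 in each of the other settings. With 100 kb, chlorophyll synthesis (4 clustered members, adjusted p = 0.0205, permutation test), chlorophyll breakdown (5, adjusted p = 0.000825) and carotenoid synthesis (3, adjusted p = 0.00623) passed, and plastid import and proteases did not (adjusted p = 0.0699). The 3 members that breakdown gained were accelerated cell death 11 genes. Carotenoid synthesis gained the short zeaxanthin epoxidase row Ila18G005720, and chlorophyll synthesis gained the glutamyl-tRNA reductase 1 rows Ila05G011670 and Ila05G011700. With 20 kb, chlorophyll synthesis had 0 clustered members. Chlorophyll breakdown and carotenoid synthesis passed, each on the same 2 clustered members as with 50 kb (adjusted p = 0.0386 each, permutation test). The Calvin cycle, plastid isoprenoid, plastid import, circadian clock (from 10 clustered members to 2) and dividing-cell (from 26 to 10) lists did not. The cause was not tested. No paired analysis was possible because the expression columns could not be assigned to samples. For the same reason the planned expression alternatives (pseudocount, filter, scaling, variance model, fold threshold, leaving out replicates, recovered reads, correlation in set tests) were not run.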
